A study of Mus musculus with 4 samples.

How the data were processed

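RNA from mouse J1 embryonic stem cells with an inducible RNAi construct against Chd4 was hybridised to 4 Affymetrix expression arrays, 2 from cells without doxycycline and 2 from cells given 5 ng/ml doxycycline for 3 days. Biotin-labelled cRNA was made from 6 ug of total RNA, per the labels' protocols. The deposited values are array intensity on a linear scale, 1 signal for each of 45101 probe sets and array, made with MAS5 per the submitters' processing notes. The version of MAS5, its scaling target and the scanner settings were not given in the sources used here. The mean of the non-control probe sets, with 2% trimmed from each tail, lay between 496.3 and 497.1 on every array, so the arrays share 1 scale. The median signal per array was 75.2 and 76.5 in the controls and 79.4 and 73.4 in the knockdown arrays. MAS5 signals of dim probe sets are noisy, and detection calls were not used here. The ratio of 3' to 5' signal was 0.793 to 0.820 for Gapdh and 1.23 to 1.30 for beta-actin over the 4 arrays, and no replicate pair shared a probe set value.

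Groups and replicate numbers were taken from the sample titles. Probe sets were named with the platform annotation, in which 34945 non-control probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were compared with a reference table through the Entrez gene ID, and 0 needed an update. Probe sets with several symbols or none and the 64 control probe sets were left out of the gene tests. Each of 18193 genes was represented by its probe set with the highest mean log2 signal over the 4 arrays. Genes whose probe set lay in the top 60% of non-control probe sets by mean log2 signal (signal 42.4 or more) were tested, which left 12615.

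Differences are log2 signal in Chd4 knockdown minus control, without a pseudocount. They were tested two-sided in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend (2 residual and 9.12 prior degrees of freedom), and p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors of log2 differences are standard errors from this fit. The Chd4 probe sets were tested in the same way among all non-control probe sets above the filter. All 2592 genes that passed had 2 groups that did not overlap. Non-overlap alone was found for 7640 tested genes (60.6%), where chance gives 33.3%. At an unadjusted p under 0.05 there were 4262 genes. Where the dimmer group's mean log2 signal was under the median of all non-control probe sets (76.0), signals under it were set to it and the fold between the group means of log2 values is given as "at least". This floor was chosen after the values were seen. Such a bound allows for dim signals only and is not a confidence limit, so the spread between arrays can reach below it.

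The genes named were fixed by a rule: Chd4, the 12 genes with the largest log2 difference in each direction among those that passed, had groups that did not overlap and had a brighter group above the median, up to 4 members of each list with the smallest p, and Pou5f1, Sox2, Nanog, Tbx3, Cdx2, Gata6 and Mbd3. Clone-like symbols and families of near-identical copies were passed over. A total of 30 gene lists was fixed together with the rule, covering pluripotency, lineages, other cell types, chromatin complexes, signalling targets, the cell cycle, stress and metabolism. Of their 809 entries 740 had a gene on the array. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, which called 5. With an estimated correlation camera called 0 lists, at a lowest adjusted p of 0.522 and with 1 list at an unadjusted p under 0.05. That form of camera rests on the 2 residual degrees of freedom of the fit, so with 4 arrays it has little power. The fry test, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes, called 13 lists, and its mixed form, for change in either direction, called 28. List members were also counted after adjustment over the list alone.

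The fit was tested on simulated data with the signals and spread of these arrays. Of 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold among 12615, it recovered 53.7%, 82.1% and 89.4% in the comparison of Chd4 knockdown with control, with 10 calls among unchanged genes. Far fewer genes were changed than passed in the data, so these shares need not hold there. With no simulated change it made 0 calls. The simulated errors were independent between genes and followed the fit's own variance model, so effects shared by an array were not simulated. Alternatives covered the pseudocount, normalization, filter, variance model, probe set choice, a replicate block, each array left out in turn, a test against a 1.2-fold change and other set tests. No other split of 2 against 2 arrays was tested, since only 3 exist.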

Results

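Transcript levels were measured on 4 single-colour Affymetrix mouse arrays hybridised with RNA from embryonic stem cells of the J1 line. The cells carried a doxycycline-inducible RNAi construct against Chd4, the ATPase of the nucleosome remodelling and deacetylase (NuRD) complex. They were grown on gelatin in medium with 15% serum and leukaemia inhibitory factor (LIF). The Chd4 knockdown group (n = 2 arrays) had received 5 ng/ml doxycycline for 3 days and the control group (n = 2) none. The series text calls the arrays of a group biological duplicates. The number of arrays limits the precision of each value. Across the 12615 genes tested, Pearson's r between the replicates was 0.986 in the control and 0.985 in the knockdown group, against 0.968 to 0.969 between arrays of different groups. Genes are not independent replicates, so these correlations describe the arrays only. The comparison of the groups asks which transcripts change in embryonic stem cells when Chd4 is depleted.

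Chd4 itself was lower in both knockdown arrays at each of its 3 probe sets. At probe set 1438476_a_at the signals were 918 and 814 in the controls and 445 and 394 in the knockdown arrays, or 48.5% of control (log2 difference -1.05 ± 0.12 SE, adjusted p = 0.000244). Probe set 1436343_at went from 894 and 822 to 551 and 420, or 56.1% of control (-0.83 ± 0.14, adjusted p = 0.00232). The brightest, 1451295_a_at, went from 2215 and 1826 to 1155 and 1480, or 65.0% of control (-0.62 ± 0.12, adjusted p = 0.00638). The last of these represents Chd4 among the genes tested, and its call ended when the variance model had no intensity trend (adjusted p = 0.146). Neither a doxycycline-treated line without the construct nor a line with another RNAi construct was analysed here. Effects of doxycycline, of the RNAi itself and of Chd4 loss therefore cannot be separated.

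Of the 12615 genes tested, 2592 changed at an adjusted p under 0.05, with 1480 higher and 1112 lower in knockdown cells. A change of at least 2-fold was seen for 462 genes, of which 339 were higher and 123 lower. These counts depend on the processing. Without the intensity trend 421 genes passed, 266 of them at least 2-fold (190 higher and 76 lower), and 1380 passed when all probe sets of a gene were averaged. In the top 40% of probe sets 256 changed at least 2-fold (177 higher and 79 lower), and without control replicate 2 the genes lower were 686. Of 1404 changed genes with a further probe set above the filter, 1005 (71.6%) had every other probe set of the same sign.

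Inhbb, which encodes an activin and inhibin subunit, showed the largest fall, 9.95-fold, from a signal of 4301 ± 11.5 to 433 ± 22 (mean ± SD, n = 2 per group; adjusted p = 2.15e-09). Tgm2, a transglutaminase, fell 5.61-fold (log2 -2.49 ± 0.15 SE, adjusted p = 2.79e-06). The guidance cue Ntn1 fell 4.90-fold (-2.29 ± 0.16, adjusted p = 4.13e-06). The homeobox gene Gbx2, a known LIF target, fell 4.77-fold from 1623 ± 71.2 to 343 ± 59.7 (adjusted p = 1.38e-06). The germ-cell RNA helicase gene Ddx4 fell 4.40-fold (-2.14 ± 0.10, adjusted p = 6.25e-07). Falls of 4.18-fold for the D-type cyclin gene Ccnd2 and 4.10-fold for the cholesterol transporter gene Abca1 followed. Other genes among the 12 with the largest falls had knockdown signals under the median of the array (76.0), so that only a lower bound of their fold is given. This bound comes from the floor and is not a confidence limit. Zadh2 fell at least 3.05-fold, Slc15a1 at least 2.57-fold, Sox3 at least 2.10-fold, Rapgef3 at least 2.08-fold and Nkx6-3 at least 1.71-fold. The adjusted p values of these genes were 0.000474, 0.00608, 0.00186, 0.00326 and 0.00663. Their mean signals went from 236 to 51.9, 209 to 52.7, 161 to 36.0, 158 to 34.2 and 131 to 34.5. The call of Slc15a1 ended without control replicate 2 (log2 -1.42, adjusted p = 0.0776) and that of Nkx6-3 without control replicate 1 (-1.83, adjusted p = 0.0597).

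All 12 genes with the largest rises had a mean control signal under that median, and their folds are likewise lower bounds from the floor. They were ranked by log2 difference without the floor. With it, all but Calml4, Slc5a4b and Crxos had bounds under the 6.29-fold rise of Otx2, which started above the median. Calml4, a calmodulin-like gene, rose at least 10.2-fold, with signals of 89.2 and 49.7 in the controls and of 786 and 896 in the knockdown arrays (adjusted p = 4.14e-06). Slc5a4b, of the sodium-glucose cotransporter family, rose at least 7.95-fold, from a mean signal of 28.5 to 606 (adjusted p = 1.62e-06). Crxos, a homeobox gene, rose at least 7.64-fold, from 44.8 to 581 (adjusted p = 2.95e-06). The fast muscle troponin gene Tnnc2 rose at least 5.50-fold, from 40.1 to 419 (adjusted p = 8.12e-06), and the tetraspanin gene Tspan8 at least 4.96-fold, from 39.0 to 377 (adjusted p = 5.89e-05). Il1r2, a decoy receptor for interleukin 1, rose at least 4.42-fold, from 27.1 to 343 (adjusted p = 4.95e-05). Afap1l2 and Slamf6 rose at least 3.85-fold and 3.33-fold, from 30.6 to 293 and from 25.4 to 253 (adjusted p = 4.63e-05 and 5.39e-05). Slc6a13, Rab25, Nlrp4c and Col2a1 rose at least 2.5-fold, 2.20-fold, 2.17-fold and 2.10-fold, with adjusted p values of 0.00747, 0.00559, 0.00643 and 0.00395. The mean signals of these genes went from 18.5 to 193, 24.5 to 168, 19.8 to 165 and 21.3 to 167. Detection calls were not used here.

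**Figure D1:**
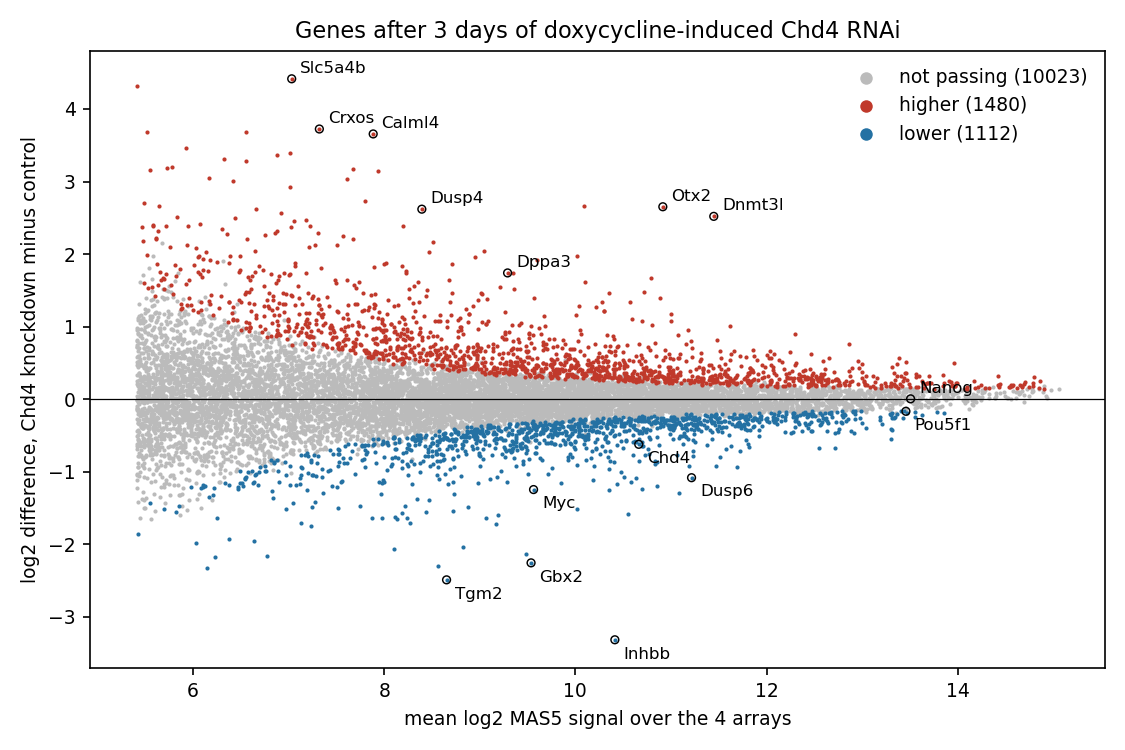
Each point is 1 of the 12615 genes tested, with its mean log2 signal over the 4 arrays on the x axis and its log2 difference, Chd4 knockdown minus control, on the y axis. Red points are the 1480 genes called higher and blue points the 1112 called lower. The rises of Slc5a4b, Crxos and Calml4 start from dim control signals, while Inhbb falls and Otx2 and Dnmt3l rise at bright signals.

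The central pluripotency factors did not pass the test over all genes. Pou5f1 had a log2 difference of -0.17 ± 0.058 SE (adjusted p = 0.065), Sox2 of 0.072 ± 0.046 (adjusted p = 0.308), Nanog of 0.0056 ± 0.046 (adjusted p = 0.949) and Tbx3 of -0.032 ± 0.069 (adjusted p = 0.795). Pou5f1 passed as lower when adjusted over its list alone (adjusted p = 0.0270), under quantile normalization (-0.20, adjusted p = 0.0352) and without knockdown replicate 1 (-0.24, adjusted p = 0.0133). The list of 34 tested core and naive pluripotency genes moved in both directions, with 9 higher and 9 lower over all genes tested and 9 and 12, with Pou5f1 among the lower, adjusted over the list alone. Dppa3, a maternal factor also found in germ cells, rose 3.34-fold (adjusted p = 5.71e-06), and Fbxo15, an early Pou5f1 target, rose 1.70-fold (adjusted p = 3.38e-05). Tet2, a 5-methylcytosine dioxygenase gene, fell 1.81-fold (adjusted p = 5.39e-05) and Tfcp2l1, a naive-state factor, fell 1.36-fold (adjusted p = 0.000262). As a set the list did not pass (adjusted p = 0.403 in camera and 0.101 in fry).

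The targets of LIF and Stat3 were lower as a set, with 6 of 13 tested genes lower and 1 higher over all genes tested, and 7 and 1 adjusted over the list alone. Their median log2 difference was -0.25 (camera adjusted p = 0.00178). The call was not held in camera with an estimated correlation (adjusted p = 0.522). The estimate, -0.058, was below the preset 0.01, so a higher correlation did not end the call. That form of camera rests on 2 residual degrees of freedom and has little power here. Beside Gbx2 and Tfcp2l1, the kinase genes Pim1 and Pim3 fell 1.47-fold and 1.36-fold (adjusted p = 0.00206 and 0.000348).

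Genes that mark the step from naive to formative and primed epiblast split in direction. Of 19 tested, 8 rose and 7 fell over all genes tested, and 8 and 8 adjusted over the list alone. Otx2, a homeobox regulator of the formative epiblast, rose 6.29-fold from a signal of 771 ± 47.8 to 4843 ± 158 (mean ± SD, n = 2 per group; adjusted p = 6.3e-09). Dnmt3l, a cofactor of de novo DNA methylation, rose 5.74-fold from 1170 ± 122 to 6694 ± 215 (adjusted p = 1.07e-08). The zinc finger gene Zic5 rose 2.77-fold (adjusted p = 1.38e-06) and the methyltransferase gene Dnmt3b rose 1.85-fold (adjusted p = 8.8e-06), while Sox3, another member, fell. The median log2 difference of the list was -0.12 and its mean 0.31, and the set test pointed up (adjusted p = 0.381 in camera and 0.0291 in fry).

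**Figure D2:**
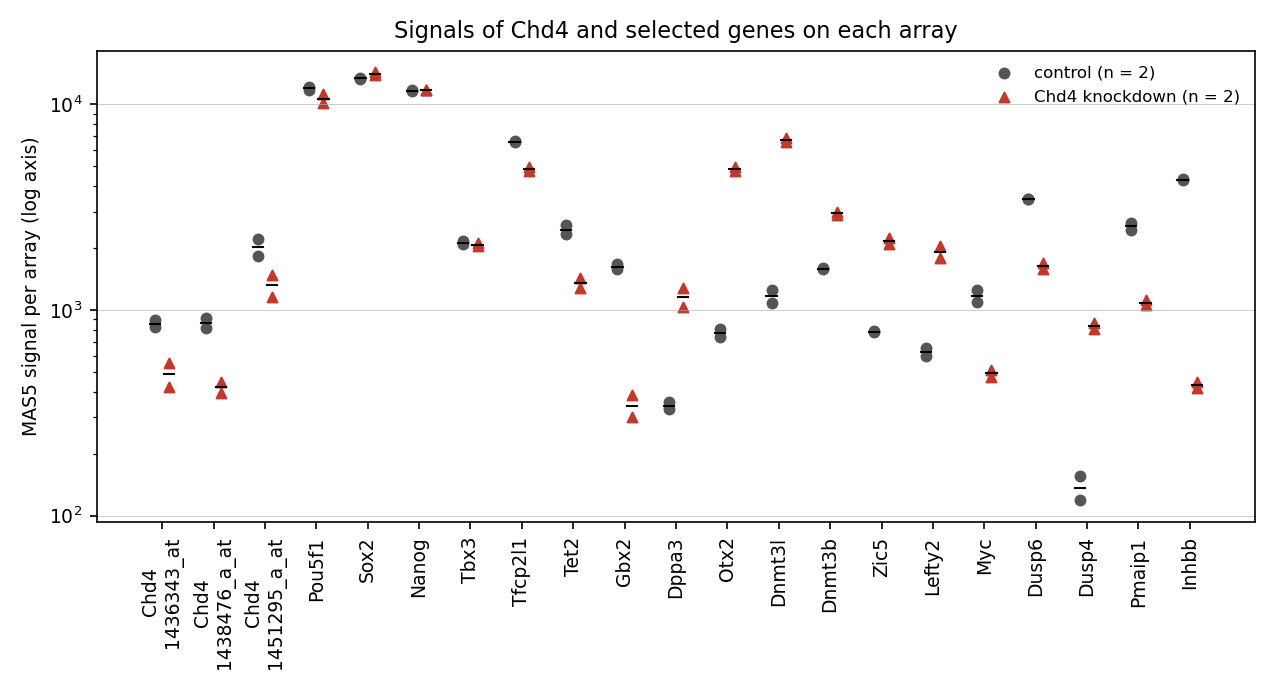
MAS5 signals of each array on a log axis for the 3 Chd4 probe sets and for selected genes. Grey circles are control arrays and red triangles Chd4 knockdown arrays (n = 2 each), and black bars are group means. Pou5f1, Sox2, Nanog and Tbx3 did not pass the test over all genes, while Otx2 and Dnmt3l rose and Gbx2, Myc and Inhbb fell.

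Genes of signalling pathways that act on these cells changed in both directions. Among 18 tested FGF and ERK feedback targets, 5 rose and 5 fell over all genes tested, and 6 and 6 adjusted over the list alone. The phosphatase gene Dusp4 rose 6.14-fold (log2 2.62 ± 0.16 SE, adjusted p = 2.85e-06), whereas its relative Dusp6 fell 2.12-fold (-1.08 ± 0.069, adjusted p = 2.85e-06). The receptor signalling inhibitor gene Spry4 fell 2.24-fold (adjusted p = 5.99e-06), with 2 of its 3 other probe sets of the same sign. Myc fell 2.37-fold (adjusted p = 2.41e-05). The set did not pass (camera adjusted p = 0.664), and its test pointed down while its median of 0.078 and mean of 0.066 were above 0. Of 15 tested Nodal and BMP targets, 6 rose and 3 fell over all genes tested, and 7 and 5 adjusted over the list alone (adjusted p = 0.381 in camera and 0.0343 in fry). The Nodal antagonist genes Lefty2 and Lefty1 rose 3.06-fold and 1.53-fold (adjusted p = 2.42e-06 and 0.00125). Id1, a BMP target, rose 1.48-fold and the inhibitory Smad gene Smad7 fell 1.5-fold (adjusted p = 0.000206 and 0.00069). Of 8 tested Wnt targets 2 rose and 2 fell over all genes tested, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.179). The median log2 difference of that list was -0.53. Its member Myc fell as above and Ccnd1 fell 1.46-fold (adjusted p = 0.000357), while Lef1 and Tnfrsf19 rose 2.05-fold and 1.96-fold (adjusted p = 0.00759 and 0.00483). The call of Lef1 ended without knockdown replicate 2 (log2 0.92, adjusted p = 0.0535), and those of Lef1 and Tnfrsf19 ended when probe sets were averaged (0.84, adjusted p = 0.123, and 0.25, adjusted p = 0.570).

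Genes of DNA replication were lower as a set. Of 32 tested, 14 fell and 0 rose over all genes tested by limma, 15 and 0 adjusted over the list alone, and 18 and 1 at an unadjusted p under 0.05. The median log2 difference was -0.18 (camera adjusted p = 4.23e-05). The call was not held with an estimated correlation of 0.083 (camera adjusted p = 0.522), a form that rests on 2 residual degrees of freedom. The replication initiation gene Gins2 fell 1.71-fold, from a signal of 2036 ± 40.1 to 1193 ± 33.0 (mean ± SD, n = 2 per group; adjusted p = 5.61e-05). The origin licensing gene Cdc6 fell 1.27-fold and the ribonucleotide reductase gene Rrm2 fell 1.22-fold (adjusted p = 0.00506 and 0.00245). Rrm1, which encodes the partner subunit, fell 1.21-fold at its brightest probe set (adjusted p = 0.00426) and had a log2 difference of 0.012 when its probe sets were averaged. In the list of 27 tested G2/M genes, 3 rose and 0 fell over all genes tested by limma, 2 and 0 adjusted over the list alone, and 6 and 0 at an unadjusted p under 0.05. Their median log2 difference was 0.053 (camera adjusted p = 0.346).

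Targets of p53 were also lower as a set, with 9 of 26 tested genes lower and 0 higher over all genes tested by limma, 10 and 0 adjusted over the list alone, and 13 and 0 at an unadjusted p under 0.05. The median log2 difference was -0.18 (camera adjusted p = 0.000117; adjusted p = 0.522 with an estimated correlation). Pmaip1, which encodes the apoptosis regulator Noxa, fell 2.35-fold (adjusted p = 2.85e-06) and Phlda3, an Akt inhibitor gene, fell 1.88-fold (adjusted p = 3.45e-05). Ccng1 and Eda2r fell 1.36-fold each (adjusted p = 0.000814 and 0.00772).

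Germline and meiosis genes were higher as a set, with 8 of 26 tested genes higher and 3 lower over all genes tested, and 13 and 3 adjusted over the list alone. The median log2 difference was 0.46 (camera adjusted p = 0.0379; adjusted p = 0.522 with an estimated correlation). The germline and meiosis list no longer passed without knockdown replicate 2 (median 0.42, adjusted p = 0.0967), in the top 40% of probe sets (0.38, adjusted p = 0.0947), with the floor at the median (0.43, adjusted p = 0.0556) or with that floor and no gene left out (0.38, adjusted p = 0.0897). Syce3 and Syce1, genes of the synaptonemal complex, rose 3.13-fold and 2.24-fold (adjusted p = 1.11e-05 and 1.39e-05). Tex19.1, a gene of germ cells and pluripotent cells, rose 2.42-fold (adjusted p = 3.01e-06). Ddx4 moved the other way. In the list of the 2-cell-like state 1 member was tested, Pramel13, at a log2 difference of 0.48 ± 0.15 SE (adjusted p = 0.0393). The call of Pramel13 ended without control replicate 1 (log2 0.47, adjusted p = 0.119), without control replicate 2 (0.50, adjusted p = 0.0991) or without knockdown replicate 1 (0.36, adjusted p = 0.211).

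The other NuRD subunits did not pass as a set in camera (adjusted p = 0.179) but did in fry (adjusted p = 0.0462), with 6 of 15 tested genes higher and 2 lower over all genes tested and the same counts adjusted over the list alone. Chd3 and Chd5, which encode the remodellers most like Chd4, rose 2.53-fold and 2.17-fold (adjusted p = 0.000251 and 0.00198), from signals of 207 ± 27.3 and 168 ± 31.7 to 525 ± 74.7 and 362 ± 34.9 (mean ± SD, n = 2 per group). The metastasis-associated subunit gene Mta3 rose 1.54-fold (adjusted p = 0.000175), with 1 of its 2 other probe sets of the same sign. Zmynd8, a NuRD-associated reader gene, fell 1.95-fold (adjusted p = 4.9e-05), although only 1 of its 4 other probe sets had the same sign. Mbd3, the scaffold subunit gene, was 1.28-fold higher (adjusted p = 0.0255), and its call ended without control replicate 2 (log2 0.23, adjusted p = 0.189), without knockdown replicate 1 (0.34, adjusted p = 0.0696) or without knockdown replicate 2 (0.36, adjusted p = 0.0539). Of 9 tested Chd remodellers other than Chd4, 3 rose and 1 fell over all genes tested, and 4 and 1 adjusted over the list alone (adjusted p = 0.346 in camera and 0.0190 in fry). Chd1l rose 1.32-fold (adjusted p = 0.00561).

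Subunits of SWI/SNF remodellers gave 3 rises and 4 falls among 19 tested genes, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.365). Smarcd3 fell 3.10-fold and Arid1b fell 2.07-fold (adjusted p = 0.000127 and 0.000204), while Phf10 rose 1.27-fold at its brightest probe set (adjusted p = 0.00351) and had a log2 difference of -0.12 when its probe sets were averaged. In the Polycomb and DNA methylation machinery 6 of 22 tested genes rose and 4 fell, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.825). Dnmt3l, Dnmt3b and the Polycomb subunit gene Pcgf6, which rose 1.27-fold (adjusted p = 0.00451), were among the rises and Tet2 among the falls. The median log2 difference of that list was -0.068 and its mean 0.070, and camera pointed down while fry pointed up. Imprinted genes gave 7 rises and 2 falls among 24 tested, and 7 and 4 adjusted over the list alone (camera adjusted p = 0.573). Phlda2 fell 2.01-fold and Grb10 fell 1.60-fold (adjusted p = 3.15e-05 and 2.72e-05), while Impact rose 1.30-fold (adjusted p = 0.00378).

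Apart from the germline and meiosis list above, no list of markers of other lineages passed in camera at the settings used here. The neural ectoderm list did under some alternatives, and fry called it and the trophectoderm list. Among 22 tested trophectoderm and trophoblast genes 5 rose and 4 fell, both over all genes tested and adjusted over the list alone (adjusted p = 0.573 in camera and 0.0291 in fry). Tfap2c, a trophoblast and germ-cell transcription factor gene, rose 2.62-fold and the galectin gene Lgals3 rose 2.73-fold (adjusted p = 1.62e-06 and 5.11e-05), while Phlda2, named above among the imprinted genes, fell. Cdx2, the caudal factor of trophectoderm, was under the signal filter and was not tested, with signals of 29.0, 22.1, 66.0 and 38.9 on control arrays 1 and 2 and knockdown arrays 1 and 2. For 20 tested genes of primitive and extraembryonic endoderm the counts were 5 higher and 3 lower, and the same adjusted over the list alone (camera adjusted p = 0.489). Rhox5, an X-linked homeobox gene, rose 3.63-fold and the collagen chaperone gene Serpinh1 rose 1.94-fold (adjusted p = 8.12e-06 and 6.44e-05). That list had a median of -0.0091 and a mean of 0.15, and its test pointed up. Gata6, the endoderm regulator, had mean signals of 45.0 and 45.7, both under the median of the array, and a log2 difference of -0.011 ± 0.49 (adjusted p = 0.992). Of 17 tested neural ectoderm genes 1 rose and 5 fell over all genes tested, and 2 and 6 adjusted over the list alone, with a median log2 difference of -0.22 (adjusted p = 0.0588 in camera and 0.0329 in fry). Camera called this list lower under 7 alternatives: the pseudocount at the 10th or 25th percentile (adjusted p = 0.0324 and 0.0329), median centring (0.0148), averaged probe sets (0.0432), the brighter group above the median (0.0438), and without control replicate 2 (0.0437) or knockdown replicate 1 (0.0183). Neurod1 and the neuronal genes Stmn3 and Nefl fell 3.13-fold, 2.04-fold and 1.68-fold (adjusted p = 9.64e-05, 0.000498 and 0.00691), and Gbx2 belongs to this list too. None of the 9 tested genes of primitive streak and mesoderm and none of the 7 tested Hox genes passed in limma, over all genes tested or adjusted over the list alone (camera adjusted p = 0.743 and 0.555). At an unadjusted p under 0.05 there were 0 in the primitive streak and mesoderm list and 1 Hox gene, Hoxc13, with signals of 101 and 111 in the controls and of 51.0 and 52.5, under the median of the array, in the knockdown arrays (adjusted p = 0.0537). Hoxc13 passed without the intensity trend (adjusted p = 0.0340), Hoxa7 without knockdown replicate 1 (0.0411) and Mesp1, of the streak list, without control replicate 1 (0.0398), each with a group mean under that median.

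Of 16 tested genes in the list of epithelial and mesenchymal genes, 8 rose and 2 fell over all genes tested, and 8 and 4 adjusted over the list alone (adjusted p = 0.0552 in camera and 0.00694 in fry). Camera called it higher with the pseudocount at the 10th percentile (adjusted p = 0.0498), median centring (0.0417), the top 40% of probe sets (0.0140) or no probe sets that can cross-hybridise (0.0451), and without control replicate 1 (0.0370) or 2 (0.0437). Epithelial and mesenchymal genes are pooled in this list, so its direction does not show a shift towards either state. The members named next have the smallest p values and are all rises, and the members that fell are not named. The splicing factor gene Esrp1 rose 2.61-fold, the keratin gene Krt18 rose 2.22-fold and the claudin gene Cldn7 rose 1.78-fold (adjusted p = 2.01e-05, 1.74e-05 and 0.000147). Epcam, an epithelial adhesion gene, rose 1.46-fold at its brightest probe set (adjusted p = 0.000119) and had a log2 difference of -0.027 when its probe sets were averaged. Of 10 tested fibroblast and feeder markers 3 rose and 0 fell over all genes tested in limma, and 4 and 0 both adjusted over the list alone and at an unadjusted p under 0.05 (adjusted p = 0.104 in camera and 0.0291 in fry). Camera called that list higher with median centring (adjusted p = 0.0484) or averaged probe sets (0.0209). The rest of its 22 genes, among them Col1a1, Col3a1, Dcn, Lum and Postn, were under the signal filter and were not tested. Thy1 rose 3.06-fold from 188 ± 16.9 to 574 ± 38 (mean ± SD, n = 2 per group; adjusted p = 3.99e-05), and the matrix protease gene Mmp2 rose 1.48-fold (adjusted p = 0.00647).

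Among genes of stress and innate sensing, 6 of 18 tested interferon response genes rose and 2 fell, both over all genes tested and adjusted over the list alone (median log2 difference 0.34; adjusted p = 0.0537 in camera and 0.0190 in fry). The call of this list changed with the processing. Camera called it higher with the pseudocount at the 10th or 25th percentile (adjusted p = 0.0464 each), median centring (0.0163), the brighter group above the median (0.0438) or the floor at the median (0.0434), and without control replicate 2 (0.0256) or knockdown replicate 1 (0.0346). Ddx58, which encodes the RNA sensor RIG-I, rose 2.43-fold and Oas1a, an oligoadenylate synthetase gene, rose 2.69-fold (adjusted p = 4.17e-05 and 0.000217), while Ifitm3 fell 1.35-fold (adjusted p = 0.00151). Of 29 tested genes of the amino acid and integrated stress response, 11 rose and 3 fell, both over all genes tested and adjusted over the list alone (adjusted p = 0.0552 in camera and 0.113 in fry). Camera called this list higher with the pseudocount at the 10th percentile (adjusted p = 0.0498), no filter (0.0335), the top 80% of probe sets (0.0489) or no probe sets that can cross-hybridise (0.0356), and without control replicate 1 (0.0255) or knockdown replicate 1 (0.0167). The stress transcription factor genes Ddit3 and Cebpb rose 1.90-fold and 1.86-fold (adjusted p = 0.00047 and 0.00011), and Phgdh, the entry enzyme of serine synthesis, fell 1.38-fold (adjusted p = 0.000119).

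Cytosolic ribosomal protein genes were higher as a set in camera, with 8 of 27 tested genes higher and 1 lower over all genes tested, and 11 and 1 adjusted over the list alone. Their median log2 difference was 0.11 (camera adjusted p = 0.00178 at the preset correlation). With an estimated correlation of 0.365, far above the preset 0.01, the camera adjusted p was 0.658. The preset thus treated these genes as less correlated than estimated. The direction turned under quantile normalization, where the median of the cytosolic ribosome list was -0.027 (camera adjusted p = 0.749). The call also ended without the intensity trend (median 0.11, adjusted p = 0.111) and with averaged probe sets (0.080, adjusted p = 0.0626), and fry did not call the list (adjusted p = 0.101). The median lay inside the central 95% of random lists matched on signal (-0.023 to 0.11). Some bright control probe sets rose as much, with log2 differences of 0.19 to 0.20 for beta-actin, 0.12 to 0.15 for Gapdh and 0.14 to 0.19 for the cre hybridisation control. Those of 18S ribosomal RNA, also bright, did not, with 0.017 to 0.061. Rplp2 rose 1.23-fold (log2 0.30, adjusted p = 0.00123). Mitochondrial ribosome genes gave 5 rises and 5 falls among 33 tested, and 7 and 5 adjusted over the list alone (camera adjusted p = 0.573), with Mrpl16 rising 1.35-fold (adjusted p = 0.000914). Nuclear genes of the respiratory chain gave 2 rises and 5 falls among 32 tested, and 3 and 7 adjusted over the list alone (camera adjusted p = 0.489), with Sdhb falling 1.19-fold and Atp5o, whose other probe set had the opposite sign, rising 1.29-fold (adjusted p = 0.00707 and 0.000599). Genes of hypoxia and glycolysis gave 4 rises and 6 falls among 27 tested, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.535). The prolyl hydroxylase genes Egln3 and Egln1 fell 1.77-fold and 1.53-fold (adjusted p = 0.00195 and 0.00209), and Kdm3a rose 1.28-fold (adjusted p = 0.00268). Cholesterol synthesis gave 0 rises and 1 fall among 19 tested genes in limma, 0 of either adjusted over the list alone, and 2 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.346).

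**Figure D3:**
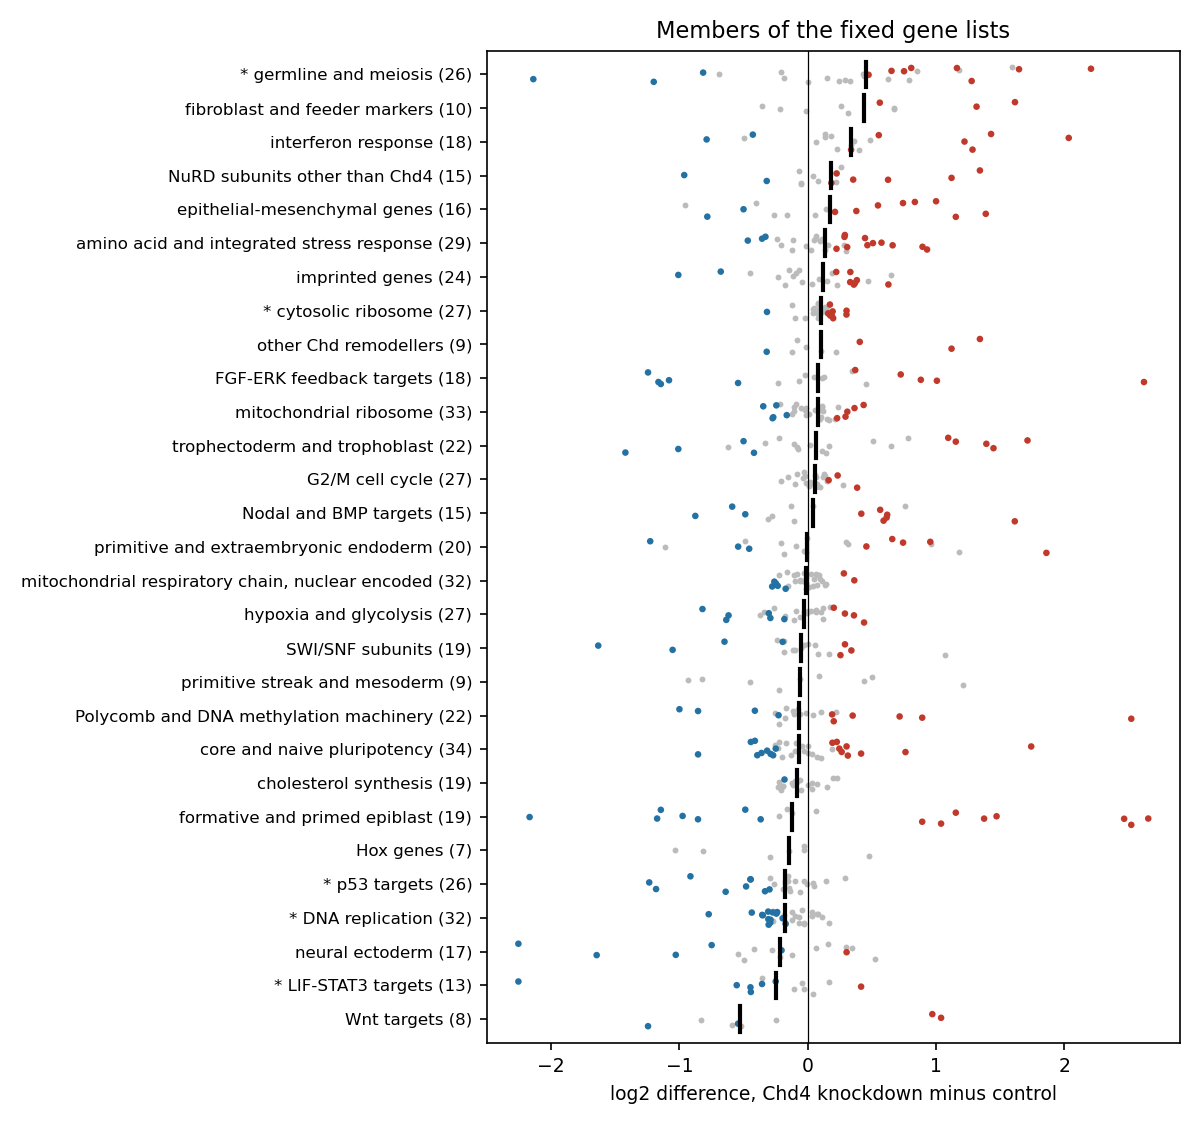
Log2 differences, Chd4 knockdown minus control, of the tested members of each gene list, whose number stands in parentheses. Red and blue points passed the test, grey points did not, black bars are list medians, and a star marks the 5 lists with a camera adjusted p under 0.05. DNA replication, p53 target and LIF-Stat3 target genes lie mostly below 0, and germline genes mostly above; the ribosomal median turns below 0 under quantile normalization.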

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

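The comparisons with the hybridisation controls and with the labelling spike-ins were chosen only after the result was seen. Control probe sets were outside the gene tests, and 8 of them were flagged because a knockdown array reached at least 2 times the highest control array and a signal of at least 100. A further set, AFFX-TrpnX-M_at, reached 13.3 times but at signals of only 1.74, 1.39, 23.2 and 2.07 on control arrays 1 and 2 and knockdown arrays 1 and 2. Of the 3 probe sets for mouse interspersed repeats, AFFX-MURINE_b1_at and AFFX-MUR_b2_at were at least 2 times higher on both knockdown arrays and AFFX-MURINE_B2_at was not. The b1 set went from 6929 and 7082 to 15468 and 15117 (2.18 times the highest control array, log2 difference 1.13), and the b2 set from 1032 and 1128 to 2855 and 2934 (2.60 times, 1.42). The third, AFFX-MURINE_B2_at, read 25885 and 27398 in the controls and 30028 and 29431 in the knockdown arrays, a log2 difference of 0.16, or 0.027 under quantile normalization. A brighter hybridisation of the knockdown arrays is argued against as the whole cause of the b1 and b2 differences: the 18 bacterial and phage hybridisation controls had a median log2 difference of 0.15 and a largest of 0.29, and the repeat differences stayed at 1.08 and 1.42 under quantile normalization. The hybridisation controls are added already labelled and do not measure labelling. The 24 spike-in probe sets that pass through labelling had a median log2 difference of 0.38. Those of thr, at 1.69 to 2.07, were high on knockdown replicate 1 alone, so the comparison over all spike-ins cannot tell. The 18 probe sets of dap, lys and phe had differences of 0.068 to 0.52, below the smaller repeat difference of 1.13. Setting thr aside was decided after its values were seen, so a brighter labelling stays open. The values of dap, lys and phe show only that these spike-ins did not rise as much as b1 and b2, which rose on both knockdown arrays. All signals were on 1 scale, so an even brightening of an array had been taken out of the controls and the repeats alike. The thr rise on 1 array stays unexplained. More repeat-containing RNA after Chd4 depletion may account for the b1 and b2 signals, as a hypothesis, although the third repeat set did not follow. Its control signals lay near the highest on those arrays (32212 and 32810), so a 2-fold rise could hardly have shown there. An effect of doxycycline or of the RNAi itself and a change in unspliced or nuclear RNA stay open, as none was tested.

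Knockdown replicate 1 alone was high at the probe sets of the thr spike-in, a bacterial transcript added during preparation. Its signals stood at 12.2, 10.3 and 11.5 times the highest control array for AFFX-r2-Bs-thr-3_s_at, AFFX-r2-Bs-thr-5_s_at and AFFX-r2-Bs-thr-M_s_at, and at 13.4, 13.0 and 13.5 times for AFFX-ThrX-3_at, AFFX-ThrX-5_at and AFFX-ThrX-M_at. Knockdown replicate 2 read 495, 170, 438, 409, 135 and 242 there, in the same order.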

How the results depend on the processing

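The alternatives compared here were fixed before the data were examined, except the 2 forms of a floor at the median signal and the requirement that the brighter group lie above it, which were chosen after seeing the data. The cause of the changes below was not tested, except where fewer genes or arrays entered by construction. Genes changed, 2592 with 57.1% higher, were within 1.5 times that count under the other alternatives but the following. Without the intensity trend 421 passed (293 higher, 128 lower, 69.6% higher; 382 shared), 266 of them at least 2-fold (190 and 76), and Chd4 (log2 -0.62) had an adjusted p of 0.146. With probe sets averaged 1380 passed (724 and 656; 1254 shared), and against a 1.2-fold change 644 (430 and 214). All probe sets in place of genes gave 1830 lower and 740 at least 2-fold, 259 of these lower. The top 40% of probe sets left 256 at least 2-fold (177 and 79), and the pseudocount at the 25th percentile 81 at least 2-fold lower. The floor was first run with no gene left out and gave 691 calls (407 and 284), 197 at least 2-fold (144 and 53), and Chd4 at -0.62 (adjusted p = 0.168). Genes at the floor on all arrays have no spread, so genes at the floor on 3 or 4 arrays were then left out: 2504 passed, 2378 of them shared, and 73.8% of 2-fold changes were rises, against 73.4%. Leaving out 1 array gave 1785 to 2145 changed genes, 1086 to 1140 higher, 686 to 1005 lower, 427 to 473 at least 2-fold, 4 to 8 gene lists and Chd4 between -0.80 and -0.44. The fewest lower genes, 686, came without control replicate 2, and without knockdown replicate 1 the rises made up 62.9% of 2-fold changes. The replicate number as a block gave 2260 changed genes, 2224 of them shared; the correlation of the replicates' deviations was 0.018, so the numbers do not show a pairing. Camera called 5 lists, 9 with the pseudocount at the 10th percentile or with median centring, and 0 with an estimated correlation, while fry called 13 and mixed fry 28. Named genes past the threshold kept direction and side in 1571 comparisons with an alternative, missed the threshold in 171 and turned in 7; with an array left out 435 kept both and 37 missed it. Named genes not past it passed in 4 comparisons with an alternative (Pou5f1, Col5a1, Sqle and Hoxc13) and 5 with an array left out (Pou5f1, Col5a1, Sqle, Mesp1 and Hoxa7). The 5 lists called by camera kept both in 69, missed the threshold in 5 (germline and meiosis in 3, cytosolic ribosome in 2) and turned in 1, and with an array left out 19 kept both and 1 missed it. Lists not called passed in 20 comparisons with an alternative and 8 with an array left out, all of them neural ectoderm, interferon response, amino acid and integrated stress response, epithelial-mesenchymal, or fibroblast and feeder lists. Signs turned in probe set averages for Rrm1 (0.012), Epcam (-0.027), Cdc20 (-0.013), Aurka (-0.032), Sdhc (0.089), Sdha (-0.45) and Phf10 (-0.12), and for Cdc20 (-0.018) without probe sets that can cross-hybridise. Nanog turned to -0.028 with quantile normalization and -0.0034 with median centring. Gata6 turned to 0.00050 with the pseudocount at the 25th percentile, 0 with the floor and no gene left out, and ran from -0.32 to 0.30 with an array left out. Hoxc6 turned to 0.010 with either floor and Hoxa7 to 0.13 with the floor and no gene left out, and with an array left out they ran from -0.68 to 0.097 and from -2.16 to 0.52. Set tests turned direction for the cytosolic ribosome list (median -0.027, quantile normalization), FGF-ERK feedback targets (0.078 without the trend and with the floor and no gene left out, 0.070 in probe set averages), the mitochondrial ribosome (0.012) and imprinted genes (0.094) in probe set averages, Hox genes (0.010, floor with no gene left out), Polycomb and DNA methylation machinery (-0.077 with median centring, -0.058 in the top 40%, 0.044 in probe set averages, -0.065 without control replicate 2, -0.040 without knockdown replicate 2) and primitive streak and mesoderm (0.086 with the brighter group above the median, 0.27 without control replicate 1, -0.021 without knockdown replicate 2). Over all 4 runs with an array left out, turned or not, the medians of these last lists ran from -0.074 to -0.027 and from -0.098 to 0.27. Signals near or under the median of the array limit what can be read of dim genes.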

Other observations

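The comparison of DNA replication genes with G2/M genes was chosen only after the result was seen. Symbol families with at least 8 tested genes were compared with all other genes, 197 in number. Only Rpl, the large-subunit ribosomal protein genes, passed with camera, with 13 of 24 higher and 1 lower and a median log2 difference of 0.15 (adjusted p = 0.00144; adjusted p = 0.988 with an estimated correlation). Cytosolic ribosomal genes as fixed in a list turned direction under quantile normalization, and their median lay at the percentile 95.95 of 10000 random lists matched on mean signal.

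Genes of DNA replication were lower while G2/M genes were not. Intensity-dependent bias is argued against, since 0% of 10000 random lists matched on mean signal had a median as low as the -0.18 of the DNA replication list, where their central 95% ran from -0.059 to 0.097. A lower share of dividing cells is argued against as the whole cause by the G2/M list, which had a median of 0.053, with 19 of 27 tested members above 0. A longer or shorter stay in parts of the cell cycle, a direct effect of Chd4 depletion and an effect of doxycycline or of the RNAi itself may each account for it and were not tested. In camera with an estimated correlation, which has little power here, the DNA replication list did not pass (adjusted p = 0.522). With 2 arrays per group the pattern is a hypothesis.

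Neighbouring genes that both changed moved in the same direction more often than chance gives; whether neighbours both change more often than chance was not tested. In the reference annotation (GRCm38.p6) 400 pairs of adjacent protein-coding genes both passed, of which 263 (65.8%) moved in the same direction. Leaving out pairs that share a symbol stem, it was 247 of 381 (64.8%), where permuting the directions gave 51.0% on average (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Signal level shared by neighbours and gain or loss of whole chromosomes are argued against as the whole cause, since directions permuted among genes of like signal gave at most 55.9% within the central 95% of draws and those permuted within chromosomes at most 56.4%, and the medians of the 20 chromosomes compared, the autosomes and X, ran from -0.062 to 0.055. A shared regional change, such as in chromatin, may account for the excess as a hypothesis, while read-through or overlapping transcripts and copy number changes of parts of chromosomes stay open, as they were not tested.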
